A study of Homo sapiens with 8 samples.

How the data were processed

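Gene expression was measured by RNA-seq in 8 libraries of nephron progenitors made from human induced pluripotent stem cells, 2 libraries in each of 4 groups. Per the labels, RNA was isolated with a micro-scale column kit (RNeasy Plus Micro) and libraries were built with the Ovation Solo RNA-Seq System, a kit for small inputs. The labels speak of cultured cells passing through a cell sorter before extraction and name no gate for that step. Groups and replicate numbers were taken from the sample titles. All 8 columns of the table were used and matched to the samples by name.

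Per the submitters' processing notes, reads were handled with bcl2fastq 2.17, Trimmomatic 0.32, TopHat2 2.1.1 and Bowtie2 2.2.3, with genome build hg19. The order of the steps, the gene annotation, any use of strand and the program that made the TPM values are not given in the sources used here. The authors deposited 1 table of values per gene and library, marked as TPM per the file headers. The deposited values were log2 of TPM, set to 0 at or below 1 TPM. That was found from the values, since 2 to the power of the values above 0 summed to between 998480 and 999031 in each library, just under the fixed total of a full TPM table. TPM carry no sequencing depth, so the depth per library and the counting error of a value are unknown. A gene at the floor may lie anywhere at or below 1 TPM, so a change from or to the floor is a lower bound. TPM are shares of a fixed total, so a class of transcripts that takes a larger share lowers the values of all others. Small RNA genes held between 10.2% and 19.1% of the summed TPM, and mitochondrially encoded genes were not listed in the table. Coordinates are those of the table. A reference genome of another build was at hand and not used.

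Of 20554 genes with values, 47 were left out, all genes on chromosome Y and XIST, as was 1 line without values. The 16901 genes above 1 TPM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3. Python 3.11.15 and matplotlib 3.10.9 drew the figures. The model had 1 mean per group and no replicate term, was fitted to the log2 values of all 8 libraries as deposited (4 residual degrees of freedom) and used empirical Bayes variances with a mean-variance trend. The plan had named log2 of the value plus 1, before it was known that the table already held log2 values. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes within a comparison, with a threshold of 0.05. Fold changes are on the log2 scale with the floor at 1 TPM, which understates changes of low genes. TPM means and SDs are over 2 libraries.

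The comparisons were GFP-positive with GFP-negative uncultured cells, each culture with uncultured GFP-positive cells, and the cultures with each other. The groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Gene lists were tested with camera, which sets the genes of a list against all others, with a preset correlation between genes of 0.01 and adjustment over 24 lists. Each was repeated with an estimated correlation, under which 0 lists passed in any comparison, and with fry, which asks whether a list's genes move one way on balance and not whether they differ from other genes. The lists, with 375 members and 366 distinct genes, covered nephron progenitor, early nephron, podocyte, nephron tubule, posterior HOX, stroma, ureteric bud, endothelium, pluripotency, neural, skeletal muscle, and cartilage and sclerotome genes, mitosis, DNA replication, targets of WNT, Notch, BMP, Activin and TGF-beta, FGF-MAPK and JAK-STAT signaling, hypoxia and glycolysis, cholesterol synthesis, immediate early and heat shock genes, and p53 targets. The members POU3F3, PECAM1, SOX1, MYOG, MYMK, DUSP6, ADM and HSPH1 were not used here. Members below the filter of 1 TPM were not tested either, and counts of members are out of those tested. That left 11 of 19 nephron tubule, 8 of 14 ureteric bud, 9 of 16 skeletal muscle, 13 of 16 podocyte and 9 of 12 pluripotency genes.

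Genes were named by 3 parts of a rule. The first took 15 genes in every comparison whatever their values. The second, called genes chosen by size, took the 6 with the largest rise and the 6 with the largest fall among those that passed, with both libraries of 1 group above both of the other and a mean of at least 2 TPM in the higher group, leaving out small RNA, histone, antisense, LINC, LOC and clone-named genes and pseudogenes. The third took up to 4 members per list by size of change among those that passed, or the 2 with the highest mean where none did, and not all of these are named. Some genes that fell under the rule are not reported here.

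The fit was tested on simulated data with 200 changed genes in each of 10 simulations per comparison. The changed genes were all drawn from those with a mean log2 value above that of 5 TPM. For GFP-positive against GFP-negative cells it recovered 7.31%, 42.5% and 90.3% of genes changed 1.5-fold, 2-fold and 4-fold, with 6.81% false calls. The same shares were 5.97%, 39.3% and 90.6% for the Activin A culture against uncultured cells, with 4.96% false calls, 6.42%, 38.2% and 90.3% for the BMP7 culture, with 6.87%, and 6.12%, 40.9% and 88.8% between the cultures, with 5.56%. The list that was moved 1.5-fold was called by camera in 10 of 10 simulations in each comparison, and unmoved lists in 0 of 230 tests. Recovery of other lists was not simulated. Noise was drawn for each gene on its own, so the simulated genes of a list did not vary together. In the data the estimated correlation between genes ran from -0.0656 in the skeletal muscle list to 0.3347 in the mitosis list. The 0 of 230 therefore cannot show how often camera calls unmoved lists whose genes vary together. Since both cultures share their controls, 100 simulations of unchanged cultures gave the overlap and the covariance expected with no effect in either culture.

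Alternatives were quantile normalization, limma without a trend, a looser and a stricter filter (above the floor in any library, and at least 5 TPM in 2), a fit of only the 4 libraries compared, the replicate number as a block, a minimum absolute log2 change of 1, 0.1 TPM added before the log, and each library left out in turn. In the last, the lone library of a group was assumed to vary like the other groups. After the data were seen, 5 more were added. They were log2 of TPM plus 1, TPM rescaled to protein-coding genes without histone and MTRNR2L genes, libraries centred on their median gene (of those above the floor in all 8 libraries), only genes above the floor in all 8 libraries, and only protein-coding genes.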

Results

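The data were gene expression values of 8 RNA-seq libraries in 4 groups of 2. All came from nephron progenitors, the embryonic cells that give rise to the nephron, made from 201B7, an established human induced pluripotent stem cell line carrying a GFP insertion in exon 1 of SIX2. Uncultured cells in the ITGA8-positive, PDGFRA-negative gate had been sorted as SIX2-GFP-positive or SIX2-GFP-negative. GFP-positive cells had also been kept for 7 days in a medium based on Activin A or on BMP7. The columns used for GFP-negative cells are headed only as ITGA8-positive, and their GFP status comes from the sample titles. Values are log2 TPM, the share of all transcripts scaled to a fixed total, with a floor at 1 TPM, so the sequencing depth is unknown. Between 14366 and 16028 genes lay above the floor per library, and 16901 genes were tested. A library at the floor entered a mean as 1 TPM. The labels do not say that replicates were separate cultures or inductions, so p-values measure only the spread between these samples, which may be technical.

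Replicates correlated across genes, which are not independent replicates, at r = 0.982 in GFP-negative cells, 0.976 in the Activin A culture and 0.974 in the BMP7 culture. The GFP-positive pair stood apart, with r = 0.956, against 0.957 between GFP-positive replicate 1 and GFP-negative replicate 2. The first principal component held 53.8% of the variance and separated cultured from uncultured libraries. The second component, with 18.5%, separated the cultures, and the third, with 9.76%, the GFP sorts.

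The comparison of GFP-positive with GFP-negative uncultured cells asked how cells with an active SIX2 locus differ from other cells of the same gate. SIX2 itself, a check of the sort, averaged 87.5 ± 21.6 TPM in GFP-positive and 19.5 ± 6.61 TPM in GFP-negative cells (SD, n = 2), a log2 difference of 2.18 (SE 0.30, limma adjusted p = 0.0186). The nephron progenitor list, which holds SIX2, was higher in GFP-positive cells by camera, not with an estimated correlation. Of its 22 members 5 passed, among them SIX2 itself and the transcription cofactor gene EYA1. Genes of neural crest and of glial or pigment cell development, SOX10, FOXD3, MITF, ERBB3, TFAP2A and TFAP2B, were higher in GFP-negative cells. In all, 240 genes passed, 104 higher and 136 lower in GFP-positive cells, but 101 higher and 75 lower with only protein-coding genes tested.

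The nephron progenitor list was higher in GFP-positive cells, with the 5 members passing over all genes and 12 when adjusted over the list alone (camera adjusted p = 5.94e-09, adjusted p = 0.282 with an estimated correlation). The list includes the sort genes SIX2 and ITGA8. SIX2 is counted in the 5 and the 12, though its difference was given by the sort. The list was not tested without it. EYA1 stood at 456.4 ± 37.2 against 243.7 ± 38.8 TPM (adjusted p = 0.0436). MEOX1 stood at 46.4 ± 2.96 against 19.6 ± 3.13 TPM (adjusted p = 0.0242) and LYPD1 at 55.6 ± 5.05 against 30.0 ± 3.45 TPM (adjusted p = 0.0427). OSR1 (80.5 ± 5.25 against 47.4 ± 0.706 TPM, adjusted p = 0.0748) and PAX8 (388.4 ± 83.6 against 228.6 ± 16.1 TPM, adjusted p = 0.0838) did not pass. The same held for WT1 (217.6 ± 34.1 against 129.1 ± 20.3 TPM, adjusted p = 0.448) and SALL1 (196.5 ± 18.5 against 145.2 ± 20.5 TPM, adjusted p = 0.430). Neither did CITED1 (16.3 ± 8.57 against 13.1 ± 2.03 TPM), PAX2 (46.7 ± 12.6 against 38.2 ± 0.469 TPM), HOXD11 (68.1 ± 12.6 against 54.5 ± 7.93 TPM), LHX1 (18.3 ± 2.06 against 18.3 ± 2.89 TPM), JAG1 (186.8 ± 14.6 against 183.7 ± 18.7 TPM) or WNT4 (1.48 ± 0.156 against 2.04 ± 0.227 TPM) pass. Of the other sort genes, ITGA8 averaged 68.6 ± 10.8 against 60.2 ± 13.6 TPM and PDGFRA 51.6 ± 11.7 against 67.3 ± 26.5 TPM, neither passing.

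Of the genes chosen by size, SYNC (chromosome 1, 33145507 to 33168361, hg19) averaged 47.5 ± 0.336 TPM and was listed at the floor in both GFP-negative libraries (at least 47.5-fold, adjusted p = 1.24e-04). NUDT3 (chromosome 6, 34254971 to 34360457) averaged 41.0 ± 5.21 against 4.09 ± 1.97 TPM, and SNX22 (chromosome 15, 64443899 to 64449680) 32.2 ± 0.164 against 4.14 ± 0.573 TPM. ATP6V1C2, a proton pump subunit gene, averaged 51.7 ± 1.64 against 6.88 ± 0.521 TPM. The readthrough gene NEDD8-MDP1 averaged 87.3 ± 2.26 against 9.19 ± 2.86 TPM. CGB2, a member of a family of near-identical genes, averaged 6.09 ± 0.353 TPM and was at the floor in GFP-negative cells. Both are uncertain, since the way reads were shared between such genes is not stated. Any use of strand is not given either, so reads from overlapping genes cannot be excluded for the other genes chosen by size.

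Genes lower in GFP-positive cells included SOX10 (chromosome 22, 38368319 to 38380556), at 1.62 ± 0.876 against 17.8 ± 4.40 TPM, and FOXD3 (chromosome 1, 63788730 to 63790797), at 1.19 ± 0.221 against 12.9 ± 4.37 TPM. Also lower were MITF, at 1.11 ± 0.154 against 11.8 ± 4.46 TPM, GAP43, at 1.77 ± 1.09 against 13.6 ± 0.244 TPM, and ERBB3, at 2.97 ± 1.04 against 24.6 ± 8.83 TPM. The stroma list was lower (camera adjusted p = 0.0076, adjusted p = 0.446 with an estimated correlation), with 1 of 17 members passing and 3 when adjusted over the list alone. That member was the proteoglycan gene LUM (3.30 ± 0.329 against 34.1 ± 4.61 TPM). The cartilage and sclerotome list was lower too, 2 of 11 members passing and 5 when adjusted over the list alone (camera adjusted p = 0.0048, adjusted p = 0.282 with an estimated correlation). COL11A2 stood at 1.47 ± 0.664 against 7.27 ± 1.53 TPM and SOX9 at 25.7 ± 1.36 against 49.5 ± 5.99 TPM. The endothelium list was lower with none of 11 members passing, though 3 did when adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.282 with an estimated correlation). EMCN averaged 2.26 ± 0.920 against 6.18 ± 0.614 TPM. The nephron tubule list was lower, with a mean log2 difference of -0.52 but a median of -0.08 (camera adjusted p = 0.0328, adjusted p = 0.479 with an estimated correlation). TFAP2B, also named with the neural crest genes, passed alone of 11 members over all genes (1.82 ± 0.303 against 14.6 ± 4.33 TPM). Adjusted over the list alone, 2 passed.

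The posterior HOX list was higher in GFP-positive cells, HOXA10 alone of 15 passing (201.4 ± 12.9 against 113.0 ± 1.82 TPM) and 3 when adjusted over the list alone (camera adjusted p = 3.41e-04, adjusted p = 0.369 with an estimated correlation). The list of FGF-MAPK targets was higher with 1 of 14 passing, ETV4 at 58.6 ± 3.53 against 32.3 ± 1.43 TPM, and 3 when adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.282 with an estimated correlation). Mitosis genes were higher as a list, 0 of 18 passing and 2 when adjusted over the list alone, TOP2A at 506.5 ± 28.1 against 406.7 ± 36.9 TPM (camera adjusted p = 3.41e-04, adjusted p = 0.470 with an estimated correlation). The DNA replication list was higher as well (camera adjusted p = 0.0148, adjusted p = 0.491 with an estimated correlation), with PCNA at 220.7 ± 3.54 against 165.9 ± 14.6 TPM. The immediate early and heat shock list was higher (camera adjusted p = 0.0228, adjusted p = 0.482 with an estimated correlation). EGR1 stood at 1144 ± 131 against 702.3 ± 235 TPM and IER2 at 299.7 ± 41.8 against 172.7 ± 57.2 TPM. Hypoxia and glycolysis genes were lower as a list (camera adjusted p = 0.0178, adjusted p = 0.479 with an estimated correlation), with LDHA at 591.6 ± 6.77 against 733.5 ± 25.0 TPM. Cholesterol synthesis genes were lower as a list (camera adjusted p = 0.0328, adjusted p = 0.491 with an estimated correlation), with HMGCS1 at 210.6 ± 11.5 against 248.7 ± 11.5 TPM. In the last 4 lists 0 members passed by limma, over all genes or adjusted over the list alone, while 2300 of all genes had an unadjusted p under 0.05.

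The other 12 lists did not pass (camera adjusted p from 0.0514 to 0.944), but held single genes that did. These were CXCR4 at 249.3 ± 34.6 against 147.6 ± 10.7 TPM and CDH6 at 21.4 ± 4.83 against 54.9 ± 14.1 TPM in the early nephron list. TFAP2A stood at 2.13 ± 0.697 against 12.7 ± 2.79 TPM in the ureteric bud list, and SOX2 at 2.62 ± 1.10 against 12.6 ± 1.397 TPM in the pluripotency list. The early nephron list had a mean log2 difference of -0.06 with a median of 0.05, the ureteric bud list a mean of -0.27 with a median of 0.03, and the Notch target list a mean of -0.10 with a median of 0.21. Small RNA genes made up 76 of the 136 lower calls and held 13.2% and 10.2% of the summed TPM in the GFP-positive libraries against 19.1% and 14.9% in the GFP-negative ones. Replication-dependent histone genes gave 17 of the 104 higher calls and held 6.49% and 5.55% against 3.86% and 3.42%.

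Many of these calls ended when a library was left out, some with folds about as large. Without either GFP-negative library the log2 difference was -3.81 and -3.30 for SOX10 (-3.55 with all) and -3.11 and -3.08 for GAP43 (-3.10). The loss there does not show that 1 GFP-negative library carried them. Without GFP-positive replicate 1, however, the log2 difference of GAP43 shrank to -2.42. In a fit of only the 4 libraries compared, limma called 0 genes, with 2351 at an unadjusted p under 0.05. The count of 240 was 115 (21 higher, 94 lower) without GFP-negative replicate 1 and 134 (19 and 115) without GFP-negative replicate 2. It was 173 (77 and 96) without GFP-positive replicate 2 and 251 (152 and 99) without GFP-positive replicate 1, so the split of the calls moved with the libraries used. With libraries centred on their median gene it was 193, 59 higher and 134 lower. Of the 25 named genes that passed, SYNC, NEDD8-MDP1, CGB2, FOXD3 and LUM passed with any 1 library left out, and the other 20 did not. The highest adjusted p without GFP-negative replicate 2 was 0.307 for TFAP2A, 0.295 for CDH6, 0.197 for SOX9, 0.165 for SOX2, 0.164 for COL11A2, 0.155 for SIX2, 0.152 for MEOX1 and 0.129 for ERBB3. It was 0.103 for SOX10, 0.0968 for ETV4, 0.0714 for HOXA10 and 0.0565 for TFAP2B. Without GFP-negative replicate 1 it was 0.273 for EYA1, 0.263 for LYPD1, 0.233 for GAP43, 0.230 for CXCR4, 0.155 for ATP6V1C2 and 0.061 for SNX22. Without GFP-positive replicate 2 it was 0.0532 for MITF and for NUDT3. The nephron tubule and cholesterol synthesis lists lost their call without any of the 4 libraries (adjusted p up to 0.237 and 0.195). The nephron tubule list passed in 7 of 16 alternatives of the data, the genes or the fit. The hypoxia and glycolysis and immediate early lists lost it without any of 3 libraries, and the stroma list without either of 2. The mean log2 difference of the hypoxia list was -0.0187 without GFP-positive replicate 1 (-0.18 with all libraries and without either GFP-negative library). That of the immediate early list was 0.21 without GFP-negative replicate 2 (0.41 with all, 0.41 and 0.40 without GFP-positive replicates 1 and 2). The stroma mean was -0.36 without GFP-negative replicate 1 (-0.56 with all, -0.51 without GFP-positive replicate 2). The DNA replication (0.250) and FGF-MAPK (0.0747) lists lost it without GFP-positive replicate 1 and the endothelium list (0.181) without GFP-positive replicate 2.

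**Figure D1:**
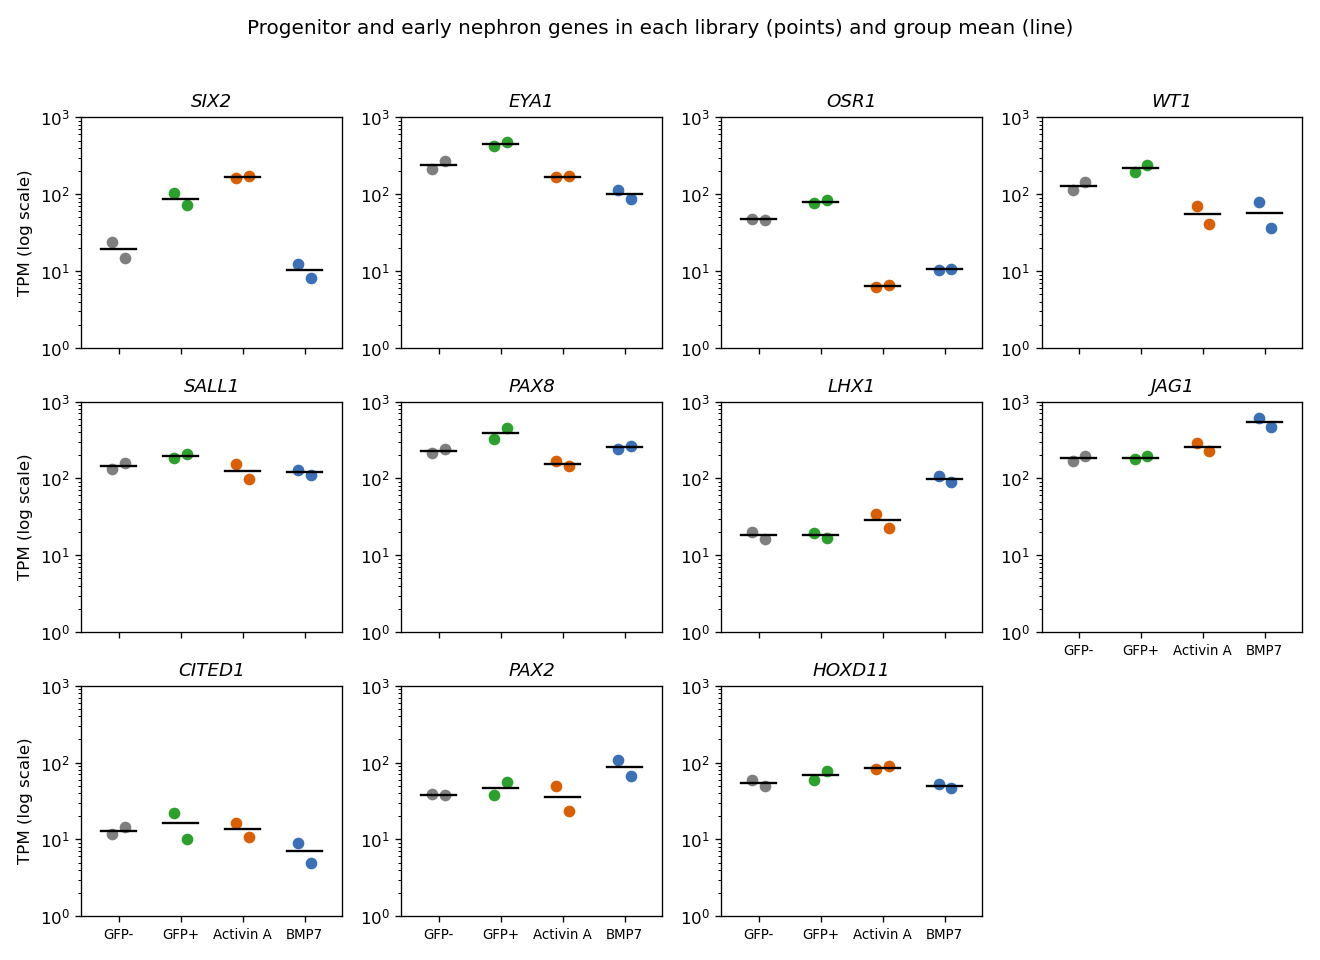
TPM on a log axis of 11 progenitor and early nephron genes in each library, with points for the 2 libraries of each group and a line at the group mean, for uncultured GFP-negative and GFP-positive cells and for GFP-positive cells after 7 days in Activin A or BMP7 medium. SIX2 averaged 168.5 TPM in the Activin A culture and 10.4 TPM in the BMP7 culture, and LHX1 28.5 and 97.8 TPM.

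The comparison of the Activin A culture with uncultured GFP-positive cells asked how far progenitors kept for 7 days in this medium differ from freshly sorted ones. SIX2 averaged 168.5 ± 6.34 TPM in culture and 87.5 ± 21.6 TPM before (SD, n = 2), a log2 change of 0.97 (SE 0.30, adjusted p = 0.0392). OSR1 fell from 80.5 ± 5.25 to 6.47 ± 0.326 TPM (adjusted p = 3.87e-05) and WT1 from 217.6 ± 34.1 to 55.5 ± 20.1 TPM (adjusted p = 0.0057). EYA1 fell from 456.4 ± 37.2 to 168.9 ± 3.94 TPM (adjusted p = 7.77e-04). By camera, though not with an estimated correlation, the lists of stroma genes, targets of Activin and TGF-beta signaling and cholesterol synthesis genes rose. Those of BMP targets, pluripotency, mitosis and immediate early genes fell. In all, 5737 genes passed, 2280 higher and 3457 lower in culture. The median of all genes lay at -0.16 on the log2 scale, against which every change below is to be read, but at -0.0355 without GFP-positive replicate 2. With libraries centred on their median gene 3074 genes were higher and 3052 lower.

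Of the 22 measured nephron progenitor genes 5 rose and 8 fell, with the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.617). LYPD1 rose from 55.6 ± 5.05 to 195.3 ± 32.7 TPM (adjusted p = 3.11e-04). SALL1 went from 196.5 ± 18.5 to 125.6 ± 37.9 TPM (adjusted p = 0.0409, and 0.0525 after centring). ITGA8 (52.98 ± 2.53 TPM in culture), PDGFRA (67.9 ± 3.77 TPM), CITED1 (13.6 ± 4.08 TPM) and PAX2 (36.2 ± 18.0 TPM) did not pass. HOXD11 (85.6 ± 5.24 TPM, adjusted p = 0.171, and 0.033 after centring) did not pass as deposited. In the early nephron list 2 of 16 rose and 7 fell, 5 and 7 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.528). PAX8 fell from 388.4 ± 83.6 to 155.6 ± 16.9 TPM (adjusted p = 0.0012), FGF8 from 30.0 ± 0.172 to 3.48 ± 0.220 TPM and HEY1, also a Notch target, from 175.3 ± 24.1 to 24.9 ± 0.101 TPM. LHX1 (28.5 ± 8.47 TPM, adjusted p = 0.0862, and 0.0386 after centring), JAG1 (258.3 ± 42.4 TPM, adjusted p = 0.073, and 0.0108 after centring) and WNT4 (1.54 ± 0.765 TPM) did not pass as deposited.

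The highest rises among the genes chosen by size were of PRG4, which encodes lubricin (chromosome 1, 186265405 to 186283688), to 523.7 ± 92.7 from 1.66 ± 0.928 TPM, followed by SPP1 and TNMD. SPP1, encoding osteopontin (chromosome 4, 88896802 to 88904563), reached 287.4 ± 131 TPM, and TNMD, encoding tenomodulin (chromosome X, 99839790 to 99855007), 213.2 ± 52.7 TPM, both from the floor before culture (at least 272.0-fold and 209.9-fold). PAPPA2 reached 200.2 ± 28.3 TPM from 1.19 ± 0.274 TPM, TM4SF1 147.2 ± 32.1 TPM and TAC1 100.5 ± 20.6 TPM, the latter pair from the floor. The deepest falls among them were of FOSB, from 162.1 ± 1.13 TPM, and LIN28A, an RNA-binding protein gene of pluripotent cells, from 91.3 ± 2.90 TPM, both to the floor. FOS fell from 984.4 ± 63.7 to 13.4 ± 3.48 TPM, HRC from 87.0 ± 7.48 to 2.205 ± 1.70 TPM, KIRREL3 from 42.2 ± 5.89 to 1.07 ± 0.0977 TPM and WFIKKN1 from 54.2 ± 5.28 to 1.46 ± 0.452 TPM.

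The stroma list rose, 11 of 17 members passing upward and none downward, the same when adjusted over the list alone (camera adjusted p = 3.48e-06, adjusted p = 0.296 with an estimated correlation). DCN reached 40.6 ± 0.486 from 2.16 ± 1.65 TPM, LUM 50.2 ± 1.88 from 3.30 ± 0.329 TPM and THY1 44.4 ± 2.99 from 4.73 ± 4.11 TPM. Targets of Activin and TGF-beta rose, 8 of 15 and the same when adjusted over the list alone (camera adjusted p = 2.42e-04, adjusted p = 0.269 with an estimated correlation). TGFBI rose from 14.5 ± 8.92 to 842.6 ± 167 TPM and FST, the gene of the Activin antagonist follistatin, from 18.1 ± 1.58 to 96.3 ± 3.03 TPM. INHBA, which encodes the Activin A subunit, rose from the floor to 33.4 ± 14.5 TPM and LEFTY1 from 1.64 ± 0.906 to 9.23 ± 3.01 TPM. BMP targets fell, 10 of 14 with 1 rising, the same when adjusted over the list alone (camera adjusted p = 3.03e-04, adjusted p = 0.308 with an estimated correlation). GREM1 fell from 74.0 ± 19.1 to 5.66 ± 2.45 TPM, MSX2 from 32.9 ± 6.78 to 3.67 ± 0.0158 TPM, ID4 from 159.8 ± 29.4 to 36.6 ± 6.74 TPM and ID2 from 579.9 ± 17.4 to 141.5 ± 0.308 TPM.

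Cholesterol synthesis genes rose, 11 of 17 with 1 falling, 13 and 1 when adjusted over the list alone (camera adjusted p = 1.67e-05, adjusted p = 0.296 with an estimated correlation). MVD rose from 19.3 ± 1.53 to 59.8 ± 3.78 TPM. The FGF-MAPK list rose, 10 of 14 with 1 falling, the same when adjusted over the list alone (camera adjusted p = 3.03e-04, adjusted p = 0.296 with an estimated correlation). SPRY4 rose from 40.9 ± 8.06 to 135.6 ± 17.3 TPM and IER3 from 35.6 ± 13.3 to 99.5 ± 9.29 TPM, whereas DUSP5 fell from 62.6 ± 0.684 to 14.4 ± 3.47 TPM. JAK-STAT targets rose, 8 of 12 with 1 falling, 8 and 2 when adjusted over the list alone (camera adjusted p = 3.03e-04, adjusted p = 0.296 with an estimated correlation). OSMR rose from 4.70 ± 0.239 to 46.1 ± 0.086 TPM and BCL3 from 3.84 ± 2.67 to 27.6 ± 9.31 TPM, with PIM1 falling from 45.5 ± 14.8 to 5.53 ± 0.285 TPM.

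The immediate early and heat shock list fell, 9 of 14 with 1 rising, 10 and 1 when adjusted over the list alone (camera adjusted p = 3.03e-04, adjusted p = 0.325 with an estimated correlation). Beside FOS and FOSB, EGR1 fell from 1144 ± 131 to 119.9 ± 71.9 TPM and EGR2 from 130.6 ± 6.24 to 7.44 ± 5.55 TPM, while the heat shock genes HSPA1A, at 32.2 TPM before and 27.4 TPM in culture, HSPA1B and DNAJB1 did not pass. The pluripotency list fell, 6 of 9 members and 8 when adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.325 with an estimated correlation). DPPA4 fell from 16.8 ± 3.90 to 2.96 ± 1.003 TPM and POU5F1 from 5.27 ± 0.341 to 1.03 ± 0.0479 TPM. Mitosis genes fell, 10 of 18 and 12 when adjusted over the list alone (camera adjusted p = 0.001, adjusted p = 0.436 with an estimated correlation). AURKB fell from 112.4 ± 7.74 to 54.3 ± 5.23 TPM and PLK1 from 114.9 ± 26.6 to 59.9 ± 8.83 TPM. The hypoxia and glycolysis list fell, 10 of 18 with 1 rising, the same when adjusted over the list alone (camera adjusted p = 0.0042, adjusted p = 0.436 with an estimated correlation). BNIP3 fell from 178.0 ± 36.4 to 33.4 ± 6.95 TPM, HK2 from 45.0 ± 0.0198 to 11.2 ± 2.43 TPM, PFKFB4 from 64.6 ± 12.3 to 14.02 ± 0.367 TPM and VEGFA from 80.5 ± 7.69 to 17.8 ± 4.35 TPM.

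The other 14 lists did not pass (camera adjusted p from 0.0651 to 0.929), with members moving both ways. Among WNT targets 4 rose and 9 fell of 14, DKK1 from 24.9 ± 0.447 to 166.1 ± 64.3 TPM and TNFRSF19 from 151.6 ± 1.402 to 38.6 ± 4.86 TPM. Among 15 posterior HOX genes HOXC11 alone rose (16.4 ± 5.77 to 48.2 ± 8.77 TPM) and 7 fell, HOXA9 from 106.0 ± 9.60 to 29.0 ± 7.57 TPM. In the ureteric bud list 5 of 8 rose, WNT11 from 3.10 ± 0.192 to 23.8 ± 5.42 TPM, and 2 fell, GATA3 from 10.5 ± 2.51 to 2.29 ± 0.846 TPM. EMCN rose from 2.26 ± 0.920 to 40.9 ± 3.22 TPM and KDR fell from 14.5 ± 4.24 to 2.66 ± 0.417 TPM in the endothelium list. CHRNA1 rose from 7.70 ± 2.51 to 61.9 ± 7.58 TPM and PAX3 fell from 41.0 ± 3.92 to 3.002 ± 0.700 TPM in the skeletal muscle list. SOX9 (25.7 ± 1.36 to 137.5 ± 15.3 TPM) and COL11A1 (6.30 ± 2.49 to 42.7 ± 5.51 TPM) rose in the cartilage and sclerotome list. SYNPO rose in the podocyte list (1.38 ± 0.304 to 21.7 ± 3.37 TPM). Notch targets gave 3 rises and 5 falls of 11 members, and p53 targets 5 falls of 14. The podocyte list had a mean log2 change of 0.11 with a median of -0.38, the endothelium list 0.11 with -0.18, the neural list 0.02 with -0.08 and the cartilage and sclerotome list 0.50 with -0.01.

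Leaving out a library moved the count to 3076 (Activin A replicate 2), 3436 (Activin A replicate 1) or 3746 (GFP-positive replicate 2), and a fit of only the 4 libraries compared gave 2795. Of 62 named genes that passed, 10 lost their call without some library. SIX2 lost it without any of the 4 and passed in 8 of 16 alternatives. Its log2 change was 0.71 (adjusted p = 0.241) without GFP-positive replicate 2 and 1.01 (0.164) without Activin A replicate 1. It was 0.93 (0.196) without Activin A replicate 2 and 1.22 (0.0637) without GFP-positive replicate 1. The highest adjusted p without Activin A replicate 2 was 0.219 for SALL1, 0.0965 for TNFRSF19, 0.0749 for HOXC11, 0.0724 for WT1, 0.0639 for IER3, 0.0518 for BCL3 and 0.0505 for DPPA4. Without Activin A replicate 1 it was 0.0857 for EGR1 and 0.0627 for PLK1.

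The comparison of the BMP7 culture with uncultured GFP-positive cells asked the same of the other medium. SIX2 fell from 87.5 ± 21.6 to 10.4 ± 3.06 TPM (SD, n = 2), a log2 change of -3.08 (SE 0.30, adjusted p = 6.52e-04). EYA1 fell from 456.4 ± 37.2 to 100.9 ± 18.3 TPM (adjusted p = 2.65e-04). The early nephron genes LHX1, from 18.3 ± 2.06 to 97.8 ± 12.5 TPM (adjusted p = 7.00e-04), and JAG1, the gene of a Notch ligand, from 186.8 ± 14.6 to 542.1 ± 100.2 TPM (adjusted p = 0.001), rose, while other members of their list fell. The tubule and ureteric epithelium genes EPCAM, CDH1 and GATA3 rose with them. In all, 4983 genes passed, 1766 higher and 3217 lower in culture. The median of all genes lay at -0.19 on the log2 scale, but at -0.0592 without GFP-positive replicate 2 and -0.1152 without BMP7 replicate 2. With libraries centred on their median gene 2779 genes were higher and 2583 lower.

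The nephron progenitor list fell, 13 of 22 with 2 rising, 15 and 3 when adjusted over the list alone (camera adjusted p = 0.0041, adjusted p = 0.407 with an estimated correlation). OSR1 fell from 80.5 ± 5.25 to 10.6 ± 0.132 TPM (adjusted p = 1.26e-04) and WT1 from 217.6 ± 34.1 to 57.9 ± 29.7 TPM (adjusted p = 0.007). ITGA8 fell from 68.6 ± 10.8 to 21.6 ± 4.19 TPM (adjusted p = 0.0017), while CRYM rose from 1.19 ± 0.262 to 28.6 ± 2.19 TPM. SALL1 averaged 120.6 ± 11.6 TPM in culture (adjusted p = 0.0396, and 0.0684 after centring). CITED1 (7.03 ± 2.95 TPM, adjusted p = 0.0918), PAX2 (87.7 ± 30.7 TPM, adjusted p = 0.115, and 0.0354 after centring), HOXD11 (49.7 ± 5.02 TPM, adjusted p = 0.0924) and PDGFRA (78.9 ± 6.12 TPM, adjusted p = 0.117) did not pass as deposited. The early nephron list rose, 8 of 16 with 5 falling, 9 and 6 when adjusted over the list alone (camera adjusted p = 0.0419, adjusted p = 0.514 with an estimated correlation). Beside LHX1 and JAG1, CCND1, the cyclin D1 gene, rose from 78.9 ± 8.33 to 635.7 ± 273 TPM and SFRP2 from 33.0 ± 2.05 to 309.1 ± 154 TPM. FGF8 fell from 30.0 ± 0.172 to 2.94 ± 1.403 TPM and PAX8 went from 388.4 ± 83.6 to 254.0 ± 18.1 TPM (adjusted p = 0.029, and 0.0711 after centring). WNT4 averaged 1.12 ± 0.173 TPM and did not pass.

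The nephron tubule list rose, 5 of 11 and none falling, the same when adjusted over the list alone (camera adjusted p = 4.23e-04, adjusted p = 0.314 with an estimated correlation). IRX1 rose from 1.07 ± 0.106 to 55.4 ± 3.99 TPM. EPCAM rose from 22.0 ± 2.92 to 237.3 ± 21.4 TPM and CDH1, encoding E-cadherin, from 6.79 ± 0.211 to 54.9 ± 28.1 TPM. The ureteric bud list rose, 5 of 8 and none falling, the same when adjusted over the list alone (camera adjusted p = 1.03e-04, adjusted p = 0.314 with an estimated correlation). TFAP2A rose from 2.13 ± 0.697 to 49.4 ± 0.553 TPM, GATA3 from 10.5 ± 2.51 to 104.7 ± 11.4 TPM and KRT18 from 47.7 ± 0.595 to 159.6 ± 8.62 TPM. Posterior HOX genes fell, 9 of 15 and 11 when adjusted over the list alone (camera adjusted p = 0.0014, adjusted p = 0.355 with an estimated correlation). HOXC8 fell from 67.7 ± 27.2 to 10.5 ± 2.25 TPM and HOXB9 from 214.5 ± 0.322 to 107.2 ± 0.485 TPM. The endothelium list rose, 4 of 11 with 1 falling, the same when adjusted over the list alone (camera adjusted p = 0.038, adjusted p = 0.314 with an estimated correlation). EMCN rose from 2.26 ± 0.920 to 48.8 ± 4.20 TPM, FLT1 from 1.81 ± 1.15 to 16.01 ± 0.353 TPM and ESAM from 1.74 ± 1.05 to 11.7 ± 0.605 TPM.

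Among the genes chosen by size, the highest rises outside these lists were of SPP1, from the floor to 159.9 ± 15.9 TPM (at least 159.5-fold), and S100A9, from the floor to 66.1 ± 13.1 TPM. They were followed by FGF14, from 1.91 ± 1.20 to 113.7 ± 28.1 TPM, IGFBP3, from 3.48 ± 2.05 to 170.5 ± 51.1 TPM, and SCG2, from 1.76 ± 0.448 to 81.4 ± 44.8 TPM. The immediate early and heat shock list fell, 10 of 14 and none rising, the same when adjusted over the list alone (camera adjusted p = 1.68e-05, adjusted p = 0.314 with an estimated correlation). FOSB (162.1 ± 1.13 TPM) and EGR2 (130.6 ± 6.24 TPM) fell to the floor, as did EGR3 (116.8 ± 27.8 TPM), which is not on the list. FOS fell from 984.4 ± 63.7 to 7.81 ± 4.68 TPM and EGR1 from 1144 ± 131 to 29.5 ± 25.9 TPM. The skeletal muscle list fell, 4 of 9 and 5 when adjusted over the list alone (camera adjusted p = 0.0192, adjusted p = 0.314 with an estimated correlation). PAX3 fell from 41.0 ± 3.92 to 1.90 ± 1.20 TPM and, to the floor, ACTC1 from 7.86 ± 0.967 and CHRNA1 from 7.70 ± 2.51 TPM. ACTN3 fell from 32.3 ± 12.7 TPM to the floor. The pluripotency list fell, 4 of 9 and the same when adjusted over the list alone (camera adjusted p = 0.0192, adjusted p = 0.407 with an estimated correlation). LIN28A fell from 91.3 ± 2.90 to 4.14 ± 1.30 TPM and POU5F1 from 5.27 ± 0.341 TPM to the floor.

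Cholesterol synthesis genes rose, 11 of 17 and 13 when adjusted over the list alone (camera adjusted p = 9.43e-06, adjusted p = 0.314 with an estimated correlation). IDI1 rose from 156.3 ± 4.66 to 275.7 ± 42.7 TPM. Mitosis genes fell, 9 of 18 and 12 when adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.407 with an estimated correlation). PLK1 fell from 114.9 ± 26.6 to 52.1 ± 2.22 TPM and TOP2A from 506.5 ± 28.1 to 326.9 ± 6.75 TPM. The DNA replication list rose, 6 of 18 with 2 falling, the same when adjusted over the list alone (camera adjusted p = 0.0455, adjusted p = 0.537 with an estimated correlation). FEN1 rose from 30.6 ± 5.49 to 62.6 ± 15.03 TPM and PCNA from 220.7 ± 3.54 to 314.6 ± 20.1 TPM, while CDT1 fell from 38.6 ± 1.404 to 24.2 ± 1.21 TPM. WNT targets fell, 8 of 14 with 2 rising, the same when adjusted over the list alone (camera adjusted p = 0.0285, adjusted p = 0.407 with an estimated correlation). NKD1 fell from 15.6 ± 2.44 to 1.504 ± 0.239 TPM and TNFRSF19 from 151.6 ± 1.402 to 19.3 ± 12.9 TPM. DKK1 rose from 24.9 ± 0.447 to 298.6 ± 66.2 TPM. JAK-STAT targets rose, 6 of 12 with 2 falling, the same when adjusted over the list alone (camera adjusted p = 0.0279, adjusted p = 0.407 with an estimated correlation). CEBPD rose from 1.60 ± 0.159 to 33.9 ± 0.283 TPM and OSMR from 4.70 ± 0.239 to 34.0 ± 9.30 TPM, whereas PIM1 fell from 45.5 ± 14.8 to 5.34 ± 0.342 TPM.

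The other 10 lists did not pass (camera adjusted p from 0.171 to 0.952). BMP targets gave 4 rises and 3 falls of 14, BMPER from 9.14 ± 0.669 to 51.9 ± 10.5 TPM, BAMBI from 24.5 ± 8.53 to 60.2 ± 2.04 TPM and GREM1 from 74.0 ± 19.1 to 2.60 ± 0.941 TPM. Targets of Activin and TGF-beta gave 2 rises and 3 falls of 15, ITGB6 from the floor to 15.5 ± 4.87 TPM and FST from 18.1 ± 1.58 to 1.77 ± 0.0491 TPM. The stroma list gave 3 rises and 6 falls of 17, POSTN from 31.8 ± 7.35 to 193.6 ± 23.0 TPM and FOXD1 from 7.99 ± 6.68 TPM to the floor. Among 11 Notch targets 3 rose and 3 fell, HES1 from 1029 ± 207 to 253.8 ± 3.71 TPM, and 6 of 14 p53 targets fell. The stroma list had a mean log2 change of -0.15 with a median of 0.26, the Notch list 0.09 with -0.21, and the cartilage and sclerotome (mean -0.32) and Activin and TGF-beta (mean -0.21) lists went upward against other genes in camera.

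Leaving out a library moved the count to 2893 (GFP-positive replicate 2) or 2934 (BMP7 replicate 2), and a fit of only the 4 libraries compared gave 988. Of 60 named genes that passed, 10 lost their call without some library. The log2 changes at the omission with the highest adjusted p follow, each with that of all libraries in parentheses. Without GFP-positive replicate 2 they were -0.61 (-0.70) for SALL1, -0.38 (-0.60) for PAX8, -0.64 (-0.68) for CDT1 and -1.84 (-2.00) for WT1. In the same fit they were 2.88 (2.92) for CDH1, 0.53 (0.51) for PCNA and 0.78 (0.81) for IDI1. Without BMP7 replicate 2 they were -2.69 (-2.69) for FOXD1 and 3.28 (3.30) for FLT1. FEN1 stood at 0.84 (1.02) without GFP-positive replicate 1. PAX8 thus shrank where its call was lost. FOXD1 was at the floor in both BMP7 libraries, so leaving either of them out could not move its change. Over the alternatives its log2 change ran from -3.67 to -1.71. The early nephron list lost its call without any of the 4 libraries (adjusted p up to 0.128) and passed in 7 of 16 alternatives. The endothelium (up to 0.130), skeletal muscle (up to 0.0839), DNA replication (up to 0.160) and JAK-STAT (up to 0.128) lists lost it without either of 2 libraries. The pluripotency list (0.120) lost it without GFP-positive replicate 2 and the nephron progenitor list (0.0576) without GFP-positive replicate 1.

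The comparison of the cultures with each other asked in which genes the media differ. SIX2 averaged 168.5 ± 6.34 TPM in the Activin A culture and 10.4 ± 3.06 TPM in the BMP7 culture (SD, n = 2), a log2 difference of 4.05 (SE 0.30, adjusted p = 2.67e-04). By camera, though not with an estimated correlation, the progenitor, stroma, cartilage and Activin target lists were higher in the Activin A culture. The early nephron, tubule, podocyte, ureteric bud and BMP target lists were higher in the BMP7 culture in the same way. In all, 1686 genes passed, 957 higher and 729 lower in the Activin A culture.

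The nephron progenitor list was higher in the Activin A culture, 10 of 22 with 3 lower, 10 and 4 when adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.356 with an estimated correlation). MEOX1 averaged 81.3 ± 7.60 against 18.0 ± 2.83 TPM, ITGA8 52.98 ± 2.53 against 21.6 ± 4.19 TPM, EYA1 168.9 ± 3.94 against 100.9 ± 18.3 TPM and HOXD11 85.6 ± 5.24 against 49.7 ± 5.02 TPM. OSR1 (6.47 ± 0.326 against 10.6 ± 0.132 TPM) and CRYM (3.16 ± 2.90 against 28.6 ± 2.19 TPM) were lower. CITED1, PAX2 (36.2 ± 18.0 against 87.7 ± 30.7 TPM, adjusted p = 0.0698, and 0.0305 after centring), SALL1 (log2 difference 0.03), WT1 (-0.01) and PDGFRA (-0.22) did not pass. The early nephron list was lower, 10 of 16 with 2 higher, the same when adjusted over the list alone (camera adjusted p = 1.60e-05, adjusted p = 0.170 with an estimated correlation). CCND1 averaged 51.3 ± 31.4 against 635.7 ± 273 TPM, FGFR4 1.42 ± 0.596 against 17.4 ± 1.16 TPM, and SFRP2 45.9 ± 29.6 against 309.1 ± 154 TPM. LHX1 averaged 28.5 ± 8.47 against 97.8 ± 12.5 TPM (adjusted p = 0.0029), JAG1 258.3 ± 42.4 against 542.1 ± 100.2 TPM (adjusted p = 0.0067) and PAX8 155.6 ± 16.9 against 254.0 ± 18.1 TPM (adjusted p = 0.0324). LEF1, also a WNT target, was higher and averaged 200.9 ± 8.26 against 60.3 ± 0.553 TPM. WNT4 lay at 1.54 ± 0.765 and 1.12 ± 0.173 TPM.

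The nephron tubule list was lower in the Activin A culture, 6 of 11 and none higher, the same when adjusted over the list alone (camera adjusted p = 3.06e-07, adjusted p = 0.128 with an estimated correlation). IRX1 stood at 1.10 ± 0.137 against 55.4 ± 3.99 TPM, MECOM at 8.47 ± 5.40 against 122.5 ± 13.99 TPM and CDH1 at 8.11 ± 5.88 against 54.9 ± 28.1 TPM. Podocyte genes were lower, 4 of 13 with 1 higher, 5 and 2 when adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.148 with an estimated correlation). CDKN1C stood at 30.6 ± 3.22 against 113.6 ± 21.0 TPM. TCF21 was higher, at 21.5 ± 1.59 against 5.57 ± 0.278 TPM. The ureteric bud list was lower, 3 of 8, and 4 with 2 higher when adjusted over the list alone (camera adjusted p = 0.0344, adjusted p = 0.356 with an estimated correlation). GATA3 stood at 2.29 ± 0.846 against 104.7 ± 11.4 TPM and KRT19 at 10.5 ± 9.30 against 89.0 ± 16.8 TPM. The endothelium list was lower, 3 of 11 with 1 higher, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.0171, adjusted p = 0.148 with an estimated correlation). FLT1 stood at 2.04 ± 1.46 against 16.01 ± 0.353 TPM and ESAM at the floor against 11.7 ± 0.605 TPM. Posterior HOX genes were higher, 6 of 15 with 2 lower, 9 and 3 when adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.360 with an estimated correlation). HOXC11 stood at 48.2 ± 8.77 against 11.1 ± 1.09 TPM, with HOXD8 lower at 14.9 ± 5.61 against 66.9 ± 6.29 TPM.

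Among the genes chosen by size, those with the highest excess in the Activin A culture were PRG4 (523.7 ± 92.7 against 1.13 ± 0.189 TPM) and NPTX2 (chromosome 7, 98246597 to 98259181), at 263.3 ± 14.7 against 1.17 ± 0.240 TPM. They were followed by TNMD (213.2 ± 52.7 TPM) and OGN (75.3 ± 12.4 TPM), both at the floor in the BMP7 culture, GAS2 (180.1 ± 7.33 against 2.56 ± 1.19 TPM) and CHRNA1 (61.9 ± 7.58 TPM against the floor). Those with the highest excess in the BMP7 culture, beside IRX1 and GATA3, were S100A9 (66.1 ± 13.1 against 1.49 ± 0.698 TPM), SUCNR1 (42.8 ± 2.40 TPM against the floor) and SCG2 (81.4 ± 44.8 against 1.84 ± 0.571 TPM). The stroma list was higher in the Activin A culture, 9 of 17 with 1 lower, 13 and 1 when adjusted over the list alone (camera adjusted p = 2.21e-08, adjusted p = 0.122 with an estimated correlation). COL6A3 stood at 225.1 ± 5.10 against 26.5 ± 9.31 TPM and LUM at 50.2 ± 1.88 against 4.06 ± 1.05 TPM. TAGLN stood at 36.3 ± 3.07 against 2.85 ± 0.594 TPM and DCN at 40.6 ± 0.486 TPM against the floor. The cartilage and sclerotome list was higher, 5 of 11 with 1 lower, 6 and 1 when adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.148 with an estimated correlation). SOX6 stood at 22.4 ± 3.40 against 4.61 ± 1.403 TPM and COL11A1 at 42.7 ± 5.51 against 8.87 ± 0.998 TPM. In the neural list, which had a median of 0, 4 of 13 were higher and 5 when adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.148 with an estimated correlation). Among them were the microtubule protein genes MAP2 at 59.0 ± 1.94 against 11.7 ± 0.916 TPM and DCX at 11.8 ± 2.06 against 2.28 ± 0.0682 TPM. Pluripotency genes were lower, 2 of 9 and the same when adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.360 with an estimated correlation). LIN28A stood at the floor against 4.14 ± 1.30 TPM and DPPA4 at 2.96 ± 1.003 against 10.1 ± 5.35 TPM.

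BMP targets were lower in the Activin A culture, 9 of 14, and 12 with 1 higher when adjusted over the list alone (camera adjusted p = 3.54e-10, adjusted p = 0.122 with an estimated correlation). MSX2 averaged 3.67 ± 0.0158 against 61.6 ± 11.4 TPM and BAMBI 9.66 ± 0.883 against 60.2 ± 2.04 TPM. SMAD6 averaged 10.7 ± 1.82 against 42.1 ± 4.22 TPM and ID4 36.6 ± 6.74 against 131.9 ± 10.4 TPM. Targets of Activin and TGF-beta were higher, 9 of 15 with 1 lower, 10 and 2 when adjusted over the list alone (camera adjusted p = 1.13e-05, adjusted p = 0.122 with an estimated correlation). TGFBI stood at 842.6 ± 167 against 18.0 ± 0.927 TPM and FST at 96.3 ± 3.03 against 1.77 ± 0.0491 TPM. ITGB6 was lower, at 1.37 ± 0.519 against 15.5 ± 4.87 TPM. FGF-MAPK targets were higher, 6 of 14 with 1 lower, 8 and 1 when adjusted over the list alone (camera adjusted p = 7.67e-06, adjusted p = 0.122 with an estimated correlation). SPRY4 stood at 135.6 ± 17.3 against 38.6 ± 2.94 TPM, PHLDA1 at 150.3 ± 3.44 against 43.1 ± 9.34 TPM and ETV1 at 97.5 ± 11.9 against 28.9 ± 1.31 TPM. DUSP5 was lower, at 14.4 ± 3.47 against 55.0 ± 5.27 TPM. Hypoxia and glycolysis genes were lower, 7 of 18, and 8 with 1 higher when adjusted over the list alone (camera adjusted p = 7.38e-06, adjusted p = 0.148 with an estimated correlation). BNIP3 stood at 33.4 ± 6.95 against 153.1 ± 30.3 TPM, the glucose transporter gene SLC2A1 at 54.4 ± 0.283 against 182.9 ± 29.7 TPM and VEGFA at 17.8 ± 4.35 against 50.8 ± 2.41 TPM.

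The other 9 lists did not pass (camera adjusted p from 0.0512 to 0.497), among them mitosis and DNA replication, in which limma called 0 members of 18 each, with 3697 of all genes at an unadjusted p under 0.05. Members of the others that passed were LGR5 (75.3 ± 1.52 against 22.7 ± 5.50 TPM) among WNT targets, HEY1 (24.9 ± 0.101 against 111.0 ± 15.7 TPM) and HEY2 (57.4 ± 13.2 against 19.7 ± 3.90 TPM) among Notch targets. SOCS2 (47.9 ± 0.579 against 4.66 ± 0.749 TPM) and STAT3 (194.0 ± 22.0 against 110.5 ± 0.0178 TPM) among JAK-STAT targets passed too, as did PHLDA3 (9.28 ± 0.152 against 3.62 ± 1.21 TPM) among p53 targets. Of the immediate early genes, EGR2 (7.44 ± 5.55 TPM against the floor) and JUN (45.2 ± 13.4 against 91.0 ± 15.4 TPM) passed. The WNT list had a mean log2 difference of 0.30 with a median of -0.05.

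Leaving out a library moved the count to 811 (Activin A replicate 2), 953 (Activin A replicate 1) or 1012 (BMP7 replicate 2), and a fit of only the 4 libraries compared gave 345. Of 66 named genes that passed, 21 lost their call without some library. The highest adjusted p without Activin A replicate 2 was 0.299 for JUN, 0.283 for DPPA4, 0.233 for PAX8, 0.192 for HOXD11, 0.175 for EYA1, 0.113 for HEY2, 0.0854 for JAG1 and 0.077 for HOXC11. Without Activin A replicate 1 it was 0.131 for PHLDA3, 0.0889 for ITGA8, 0.0888 for OSR1, 0.065 for SOX6, 0.0644 for TCF21 and 0.0627 for COL11A1. It was 0.136 for CDH1, 0.104 for CRYM and 0.103 for SFRP2 without BMP7 replicate 1, and 0.173 for LGR5, 0.124 for FLT1, 0.110 for EGR2 and 0.107 for KRT19 without BMP7 replicate 2. The posterior HOX (adjusted p up to 0.0858) and ureteric bud (up to 0.128) lists lost their call without any of 3 libraries, and the cartilage and sclerotome (up to 0.118) and pluripotency (up to 0.0789) lists without either of 2. The neural list (0.0858) lost it without BMP7 replicate 1 and the podocyte list (0.0828) without BMP7 replicate 2. The ureteric bud list passed in 10 of 16 alternatives and the podocyte list in 13.

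**Figure D2:**
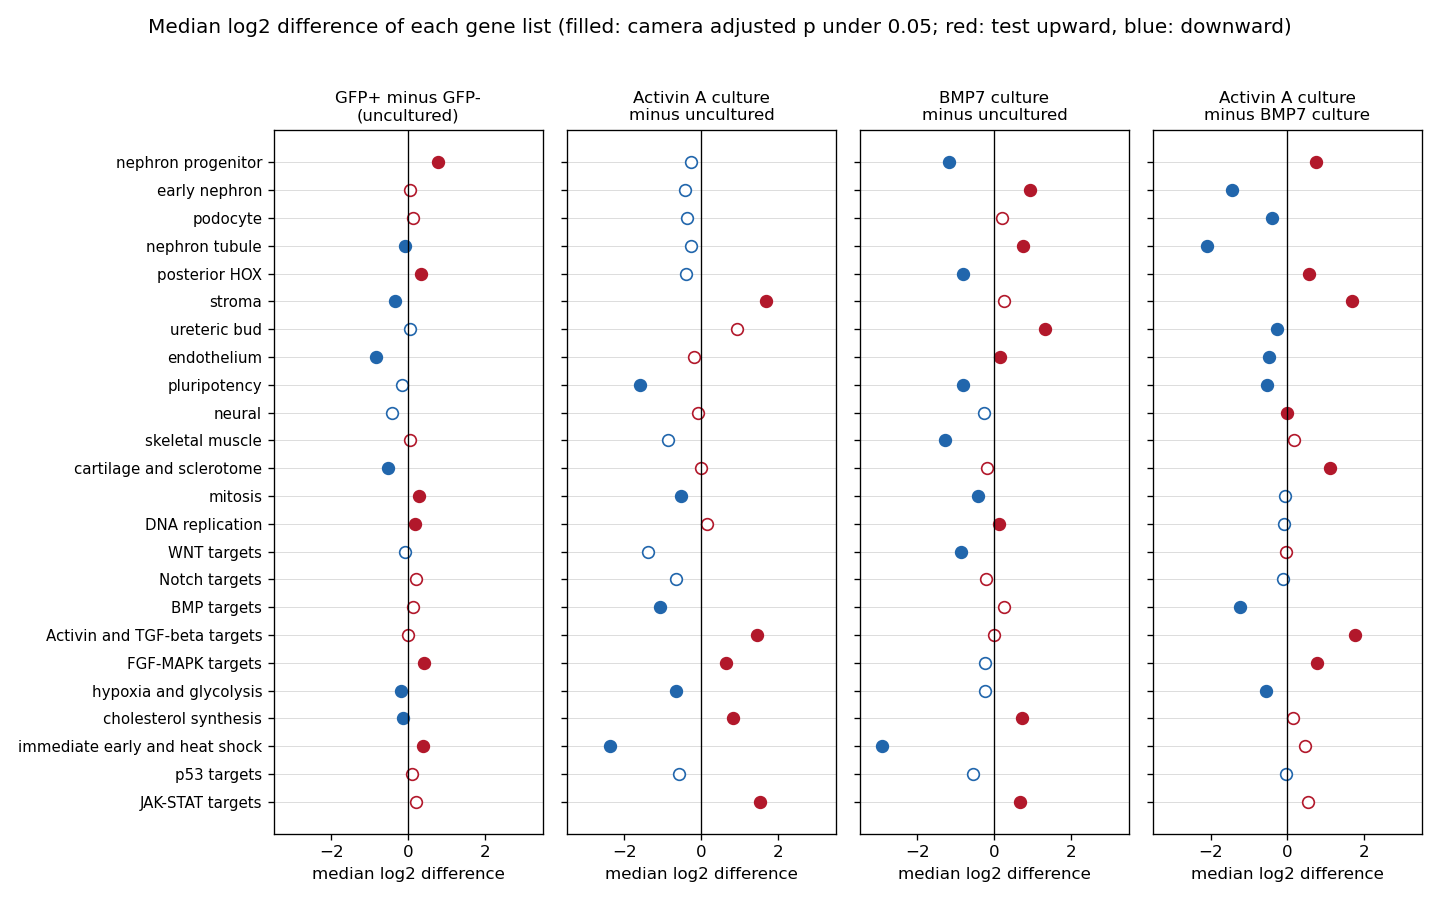
Median log2 difference (horizontal axis, log2 units) of the measured members of 24 gene lists in the 4 comparisons, 1 point per list, filled where the camera adjusted p was under 0.05 and coloured by the direction of that test, red upward and blue downward. Camera called 12 lists between the GFP sorts, 10 and 14 in the Activin A and BMP7 cultures against uncultured cells and 15 between the cultures.

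Both cultures were compared with the same uncultured libraries. They shared 1098 genes that rose and 2381 that fell, against 238.2 and 658.0 for independent lists of these sizes. Unchanged cultures simulated against the same libraries gave on average 0 shared rises and 0.01 shared falls, which is chance with no effect and not what shared controls add where many genes change. The covariance of the log2 changes across genes was 0.80, against 0.06 simulated, and the correlation 0.71 against 0.50. A split of the 2 uncultured libraries would leave 1 for each culture and was not made, so part of the excess may come from the shared controls. FOS, FOSB, EGR1, LIN28A, OSR1 and EYA1 were among the shared falls and SPP1, EMCN and OSMR among the shared rises, and 280 of the 3479 shared genes also differed between the cultures. Another 112 genes passed in opposite directions, all of them also called between the cultures, which follows from the arithmetic of opposite changes. Of these, 73 were higher with Activin A and lower with BMP7, such as SIX2, MEOX1 and CHRNA1, and 39 went the reverse way, such as GATA3 and MSX2. The count of 3479 was 1950 without GFP-positive replicate 2, 1995 and 2138 without Activin A replicates 2 and 1, and 2153 without BMP7 replicate 2.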

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

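The test of scaling in this part was chosen only after the result was seen. In 19 of the 150 genes named, each culture differed from the same uncultured GFP-positive libraries in an opposite direction and the cultures differed from each other, all by limma. Opposite changes from the same libraries add up to the difference between the cultures, so the last call follows from the others. Many of the 150 genes were named for the size of their changes here. Their share is thus no estimate for all genes, of which 112 of 16901 passed in this way. In the 13 genes higher with Activin A and lower with BMP7, the log2 difference, Activin A minus BMP7, was 7.83 for NPTX2, 6.22 for OGN, 6.22 for GAS2, 5.95 for CHRNA1, 5.77 for FST and 4.05 for SIX2. It was 3.69 for TAGLN, 3.37 for SOCS2, 2.31 for SOX6, 2.18 for MEOX1, 1.82 for PHLDA1, 1.75 for ETV1 and 1.74 for LEF1. In the 6 genes lower with Activin A and higher with BMP7 it was -1.98 for SMAD6, -2.64 for BAMBI, -3.68 for FGFR4, -4.01 for MECOM, -4.06 for MSX2 and -5.56 for GATA3. The change against uncultured cells that came nearest to the threshold was that of PHLDA1 with Activin A (0.51, adjusted p = 0.0485), followed by NPTX2 with BMP7 (-1.63, adjusted p = 0.0416).

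In the Activin A culture SIX2 stood above its level in uncultured GFP-positive cells while EYA1, OSR1, WT1, SALL1 and the early nephron list gene PAX8 fell. SIX2 was not alone, since of 22 nephron progenitor genes 5 rose, among them LYPD1 and MEOX1, and 8 fell. The list did not pass (camera adjusted p = 0.617). Scaling of the libraries did not account for SIX2 going against EYA1, OSR1, WT1, SALL1 and PAX8. SIX2 stood at a log2 change of at least 0.927 with libraries rescaled, centred or quantile normalized, with the median of those 5 genes at -1.29 or lower in each. Rescaling and centring shift all genes of a library alike, so the distance between the genes was no test of them. The rise of SIX2 itself was weak. With quantile normalization it went from 0.97 (SE 0.297) to 0.927 (SE 0.311), and the slightly smaller change and wider error ended the call (adjusted p = 0.057). The call was also lost without a trend (0.0688), with the looser filter (0.0549), in a fit of only the 4 libraries compared (0.0687) and without any 1 of these 4 libraries, with log2 changes of 0.71 to 1.22, all upward. It passed in 8 of 16 alternatives, as did the fall of SALL1, which went from -0.68 to -0.3633 without Activin A replicate 2 (adjusted p = 0.219). What stays open, and was not tested, is a changed share of SIX2-expressing progenitors among the cells, a sort for GFP after culture, for which the labels name no gate, and an effect of the medium on SIX2 itself, which is a hypothesis.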

How the results depend on the processing

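Of the alternatives, 5 were chosen after the data were seen. Counts of genes moved most with the spread a fit could draw on, and counts of lists with an estimated correlation. With only the 4 libraries compared limma called 0 genes between the GFP sorts (2351 at an unadjusted p under 0.05), 2795 and 988 in the Activin A and BMP7 cultures and 345 between the cultures. Such a fit has fewer libraries to estimate the spread. The fit of all 8 libraries pools the spread of the groups, while the GFP-positive pair was the least alike (r = 0.956, against 0.974 to 0.982 in the others). Comparisons with GFP-positive cells may therefore rest on too small a spread, which was not tested. Leaving out 1 library gave 115 to 251, 3076 to 5529, 2893 to 4982 and 811 to 1154 genes in the same order, 1950 to 3704 genes shared by the cultures, and 6 to 9, 10 to 11, 10 to 11 and 11 to 15 lists. A minimum log2 change of 1 gave 3708, 3232 and, for shared genes, 2144, by construction. Lists called were 0 in each comparison with an estimated correlation. That setting refers camera to the 4 residual degrees of freedom of the fit, which raises p by construction, and for most but not all lists the estimate also lay above the preset correlation. They were 4 between the GFP sorts and 19 in the Activin A culture by fry, which asks another question. Of the 12 lists that camera called between the GFP sorts, 3 passed by fry: nephron progenitor, cartilage and sclerotome, and FGF-MAPK targets. The others of the 12 passed neither by fry nor with an estimated correlation. The neural list, not called by camera there, was lower by fry (adjusted p = 0.0329). Lists called were 9 in the BMP7 culture among genes above the floor in all 8 libraries, an added alternative whose cause was not tested. Apart from the replicate block, all other counts stayed within 1.5 times. Replicate numbers do not pair the samples by the labels, and deviations of same-numbered libraries correlated across genes at -0.05 to 0.09. With a replicate block 148 genes were called between the GFP sorts, 5380 and 4603 in the cultures, 1495 between them and 3182 shared, and the same 12, 10, 14 and 15 lists by number. The split of calls moved with the libraries, and higher calls between the GFP sorts made up 14.2% to 60.6% with 1 library left out. It also moved with scaling, and the median gene lay below 0 in both cultures. Higher calls made up 43.3% between the GFP sorts, 30.6% after centring, 57.4% among protein-coding genes and 52.7% among genes above the floor in all 8 libraries. They made up 39.7% and 50.2% in the Activin A culture (48.7% with quantile normalization), and 35.4% and 51.8% in the BMP7 culture (49.4% with quantile normalization).

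No named gene that passed changed direction in any alternative run. Signs turned only for genes that passed in neither fit, all with values near 0 or wide apart in the replicates, and the cause was not tested. With quantile normalization these were LHX1 (-0.088) between the GFP sorts, CITED1 (0.0137) and WNT4 (0.34) in the Activin A culture, WNT4 (0.0098) in the BMP7 culture and SALL1 (-0.0252) between the cultures. With libraries rescaled they were LHX1 (-0.0633) and JAG1 (-0.0433) between the GFP sorts and WNT4 (0.0191) in the Activin A culture, and with libraries centred LHX1 (-0.0705), JAG1 (-0.0505), WNT4 (0.11) and, between the cultures, SALL1 (-0.0278). With log2 of TPM plus 1 WNT4 stood at 0.004 in the Activin A culture. With 1 library left out, log2 differences between the GFP sorts ranged from -0.34 to 0.79 for CITED1, -0.16 to 0.17 for LHX1, -0.0174 to 0.54 for PAX2, -0.078 to 0.13 for JAG1, -0.0353 to 0.43 for ITGA8 and -0.76 to 0.0684 for PDGFRA. In the Activin A culture they ranged from -0.76 to 0.37 for CITED1, -0.56 to 0.50 for WNT4 and -0.97 to 0.0943 for PAX2, and between the cultures from -0.28 to 0.34 for SALL1, -0.16 to 0.90 for WNT4 and -0.56 to 0.54 for WT1. Depth is not known from TPM, so genes near the floor, such as WNT4 at 1.12 to 2.04 TPM, carry an unknown counting error. A 2-fold change was recovered in under 43% of simulated genes averaging above 5 TPM, and recovery of lower genes was not simulated.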

Other observations

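In this part the tests of neural crest markers and of 1 GFP-negative library were written before their values were seen, and the other tests were chosen only after the result was seen. Of 79 ribosomal protein genes, 39 (49.4%) fell by limma in the Activin A culture against uncultured GFP-positive cells and 1 rose, at a median log2 change of -0.43 (-0.29 after centring). Of all genes 20.5% fell. The ribosomal protein genes held 15.2% and 14.3% of the summed TPM in the uncultured GFP-positive libraries and 11.1% and 10.8% in the Activin A libraries. In the BMP7 culture 6 fell and 3 rose, at a median of -0.15 that turned to 0.05 after centring, with shares of 13.1% and 13.4%. Between the cultures 2 of the 79 passed, both lower with Activin A, at a median of -0.27.

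Among genes listed neither as protein-coding nor as small RNA, mostly non-coding RNA genes and pseudogenes, far more fell than rose in both cultures, though most did not pass. Neither this class nor the ribosomal protein genes were tested against other genes. With Activin A 528 of 1644 (32.1%, against 20.5% of all genes) fell and 52 rose, at a median of -0.72 (-0.58 after centring), and with BMP7 520 (31.6%, against 19.03%) fell and 31 rose, at a median of -0.76 (-0.56 after centring). The number of genes above the floor was also lower, 14366 to 14443 in the cultured libraries against 15173 to 16028 in the uncultured ones. Many of these genes lie near the floor and pseudogenes share sequence with their parent genes, so single values are uncertain.

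Neural crest genes (SOX10, FOXD3, MITF, ERBB3, TFAP2A and TFAP2B) were higher in GFP-negative than in GFP-positive cells. Rescaling and centring shift all genes of a library alike, here by at most 0.198 log2 units, so a difference of this size was bound to remain. The median log2 difference stayed at -3.28 with both. Without either GFP-negative library the medians were -2.82 and -3.59. These genes were named because they passed in the same libraries, so this outcome was nearly given and cannot decide whether 1 library carried the difference. A candidate explanation, as a hypothesis, is cells of neural crest type in the GFP-negative sort, although the gate asked for ITGA8-positive and PDGFRA-negative cells. Of 16 further markers, 0 of them in the 24 lists, 15 were tested and 14 averaged higher in GFP-negative cells, 9 of them at an unadjusted p under 0.05 and 4 passing, with a median of -0.76 (camera p = 1.88e-10, p = 0.0162 with an estimated correlation). EDNRB and MOXD1 were among the called ones, but 8 of the 15 averaged at least 5 TPM in GFP-positive cells too, so expression of these genes by progenitors without GFP stays open.

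Immediate early genes stood high in uncultured cells, with FOS at 984.4 and 781.3 TPM, FOSB at 162.1 and 135.0 TPM and EGR1 at 1144 and 702.3 TPM in GFP-positive and GFP-negative cells, and low in both cultures. Centring shifts all genes of a library alike, here by at most 0.198 log2 units, so a difference of this size was bound to remain. The median of the 14 members of the list lay at -2.37 and -2.93 in the Activin A and BMP7 cultures as deposited, and at -2.23 and -2.73 after centring. The GFP-negative libraries stood 2.12 and 2.197 log2 units above the cultures in the median of the list, so the high level was shared by both uncultured sorts. Per the labels cultured cells also passed through a cell sorter, so sorting as such was common to all groups. Other handling at collection and the absence of culture cannot be told apart here, since both uncultured groups share both. A response of these genes to 7 days in culture is a hypothesis that the design leaves untested.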
